A study of Bacillus amyloliquefaciens with 4 samples.

How the data were processed

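Total RNA of Bacillus amyloliquefaciens SQR9, a plant-associated soil bacterium, was sequenced in 4 libraries. Per the labels' protocols, cells were grown without shaking in multiwell plates in diluted MSgg, a minimal medium used to grow Bacillus biofilms, and concentrated maize root exudates or water were added. Per the labels' protocols, a kit for removal of ribosomal RNA was used before cDNA synthesis, and libraries followed a standard Illumina protocol. The labels give a treatment by time design with 1 library in each of 4 groups (water control or exudates, 24 h or 48 h), so no group has a replicate. Bowtie2 was the aligner named in the submitters' processing notes, without a version. The counting program, its handling of strand and of reads that fall in overlapping genes, and the treatment of reads with several matches are not given in the sources used here.

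The authors deposited 2 tables of 4078 locus tags each, with raw read counts per locus, values headed RPM and FPKM, a log2 fold change and a q-value. Both tables name the SQR9 genome in their headers. The files do not pair the locus tags with gene names, and no annotation was used here, so loci are given by tag. Tag numbers run in steps of 10 without gaps, and the position of a locus is given below as its row in tag order. The coding length was recovered for 4077 loci as the ratio of the deposited RPM and FPKM values (median 738 bp, all multiples of 3).

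Only the deposited read counts were used as measurements. Where ratios of the deposited RPM values are given as an alternative, 1 was added to each value before taking log2. The values headed RPM in the authors' deposited tables are not on 1 scale. In the larger set of 3238 loci the divisor shrinks down the table. It falls by the reads of the row, within 2 reads, in 1378 of 1898 adjacent pairs of rows (72.6%), and the total implied for the 24 h control in the last row is 2560 reads. In a second set of 803 loci the value headed RPM had already been divided by length, with 1 total per library. That total equals the sum of the reads in 3 libraries and is 55.3% of it in the 24 h control. The deposited log2 fold changes also differ between these sets. In the control table they give 48 h over 24 h in the larger set and 24 h over 48 h in the second. In the exudate table they give exudates over control at 48 h in the larger set and exudates at 24 h over exudates at 48 h in the second. The deposited q-values come from a test that is not named in the sources used here and that had 1 library per group, and they were not used. A deposited fold was taken to match a ratio of counts within 0.003 on the log2 scale. By this rule 37 loci fell in neither set.

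Rows with a spreadsheet error in place of a count (4) were left out, which leaves 4074 loci. A further 227 pairs of loci have identical counts in all 4 libraries (at least 20 reads in total), 218 of them 2 rows apart. At least 1 count of such a pair may belong to another locus, so these loci are marked as uncertain where named and were left out of the neighbour analyses. They were kept in the main counts.

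Counts were scaled with the trimmed mean of M values (edgeR 4.0.16). A log2 ratio of 2 libraries was computed with a pseudocount of 0.5 reads scaled to library size, for loci with at least 20 reads in 1 of the 2. With 1 library per group there is no test between 2 libraries, and a locus is called higher or lower by size, at a ratio of at least 2-fold. Each ratio carries an exact (Clopper-Pearson, conditional binomial) 95% interval, which covers counting error only, not the variation between cultures. A run was defined, after the data had been seen, as at least 5 loci adjacent in tag order that were all at least 2-fold apart in 1 direction. Run counts were set beside 1000 shuffled orders. Correlations across loci carry a 95% interval from 2000 bootstrap draws of blocks of 20 adjacent loci. That interval covers the choice of loci within these libraries, not the variation between cultures. Ratios of exudates to control at 48 h still had r = 0.15 at a distance of 20 rows, so it may be too narrow.

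The fit with residual degrees of freedom was an additive model of treatment and time over all 4 libraries, with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. It has 1 residual degree of freedom. Its spread is the departure from additivity, so it asks whether a difference is alike at both times or in both media, not whether it exceeds the variation between cultures. The same script, tested on simulated counts with the real means and library sizes, 3819 loci and the estimated dispersion of 0.0742, recovered 14% of the 2-fold and 89% of the 4-fold treatment effects of the average exudate effect, with 1 false call. Every simulated locus had the same dispersion and an effect alike at both times. Real loci may each have their own spread, so these shares may not hold for the real counts. DESeq2 1.42.0 and limma 3.58.1 were run as alternatives, with R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

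The design, the thresholds, the alternatives and 25 gene lists with 1031 symbols were fixed before the data were examined. None of the symbols occurs in the tables (0 found), so no list was evaluated. The rule for named genes took the 8 largest ratios in each direction per comparison among loci with a symbol, up to 4 members of each list, a set of fixed symbols, and the 5 largest calls in each direction of the additive fit. No locus carries a symbol, so only the 2 tags with the largest ratio per direction and comparison are named. The loci with the largest share of reads, the positions of runs and the neighbours of named tags were chosen after their values were seen. Alternatives were other scalings, pseudocounts, count filters and fold thresholds, the deposited RPM values, other tools, each library left out of the additive fit, and, added after the data had been seen, the identical pairs and the second set of loci left out.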

Results

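The transcriptome of Bacillus amyloliquefaciens SQR9 was compared between static cultures that received maize root exudates and cultures that received water, at 24 h and 48 h. The total of reads assigned to loci was 6625261 in the 24 h control, 5270617 in the 48 h control, 5185001 with exudates at 24 h and 5918874 with exudates at 48 h. Of 4074 loci, between 4060 and 4064 had a read in each library and between 3668 and 3752 had at least 20. A count of 0 allows up to 3 reads of a library's total, for counting error only. Each group was a single library. All differences between 2 libraries below therefore have no replicate check, and their intervals cover counting error only.

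Reads were more concentrated on a few loci with exudates at 48 h than in the other libraries. The 41 most abundant loci of each library held 31.3% of its reads there, against 21.5% in the 24 h control, 22.4% in the 48 h control and 19.97% with exudates at 24 h. The 2 most abundant loci were named after their values were seen. V529_29530 took 4.47% of the reads with exudates at 48 h (exact 95% interval 4.45 to 4.49), against 1.89% in the 48 h control and 1.14% with exudates at 24 h. V529_09820 took 4.34% with exudates at 48 h (4.33 to 4.36), against 2.05% and 1.08%. Across 3819 loci the libraries were most alike between control and exudates at 24 h (Pearson r = 0.97 of log2 levels) and least alike between 24 h and 48 h with exudates (r = 0.92).

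At 24 h, a small part of the loci differed by size between exudates and water. Of 3744 loci kept, 153 were at least 2-fold higher with exudates than with water and 122 at least 2-fold lower, 7.35% together. The counting interval excluded a ratio of 1 for 273 of these 275 loci, which follows largely from their choice by a ratio of at least 2-fold. With the deposited RPM values the counts were 106 higher and 345 lower, and 248 of the lower loci were in the second set, where the total used for the 24 h control is 55.3% of its reads. V529_39420 had the largest ratio, 6.52-fold higher with exudates (interval 4.99 to 8.77), with 316 reads against 62. V529_39380 was 4.78-fold higher (3.56 to 6.64), but its counts are identical to those of another row and are uncertain. The only run of adjacent loci in this comparison lay at positions 3936 to 3945 and includes V529_39420. Its 8 loci, identical pairs left out, were higher by a median of 3.52-fold. V529_09000, a locus of the second set, had the lowest ratio, 9.31-fold lower with exudates (5.23 to 19.8), with 11 reads against 137. V529_31610, a long coding region of 7125 bp, was 7.81-fold lower (4.64 to 15.1). The next lower ranks, 3 to 7, were rows adjacent to this locus or to each other, lower by 5.73-fold to 7.75-fold. An identical pair among them is uncertain and was left out of the run analysis, so no run was counted there. No run among 1000 shuffled orders of the loci in this comparison reached 5 loci.

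At 48 h, more loci differed, and part of the lower ones lay in runs. Of 3787 loci kept, 151 were at least 2-fold higher with exudates and 205 at least 2-fold lower, 9.40% together, and 32 of the lower loci but 5 of the higher ones passed 4-fold. The balance depended on the scaling. With total reads in place of the trimmed mean, the median log2 ratio of all loci moved from -0.01 to -0.18 and the counts became 83 higher and 325 lower. With the deposited RPM values they were 80 and 320, and with median-ratio factors 175 and 177. All 8 runs were lower with exudates and held 61 loci, and none of 1000 shuffled orders gave a run. The longest, at positions 1559 to 1571, held 13 loci lower by a median of 4.21-fold, and a second at positions 1578 to 1585 held 8 loci lower by a median of 3.80-fold. Another 2 runs, at positions 129 to 137 and 146 to 151, were lower by medians of 2.27-fold and 2.23-fold. V529_26030 was 6.19-fold higher with exudates (5.70 to 6.74), with 4066 reads against 657, and V529_26000 was 5.14-fold higher (4.82 to 5.49). The rows between these tags held ranks 3 and 4, at 5.02-fold and 4.04-fold higher. This block of higher neighbours is shorter than the 5 loci of the run rule, which was set after the data had been seen. V529_33540, a coding region of 228 bp in the second set, was 7.23-fold lower (4.44 to 13.1), with 17 reads against 126. V529_14910, at 179 reads against 1047, was 5.83-fold lower (4.98 to 6.88) and lies in a run of 6 lower loci at positions 1489 to 1494.

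**Figure D1:**
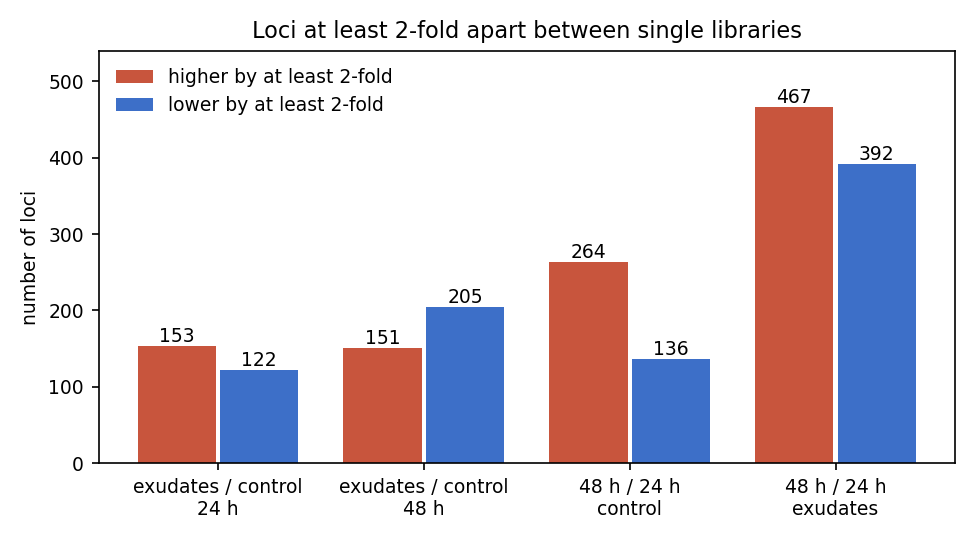
Number of loci at least 2-fold higher (red) or lower (blue) in each comparison of 2 single libraries. The bars for 48 h over 24 h with exudates (467 higher, 392 lower) are the tallest of the 4 comparisons.

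The exudate effects at the 2 times, which share no library, were close to unrelated across all loci. Over 3712 loci kept at both times, Pearson's r of the log2 ratios was -0.04 (block bootstrap interval -0.10 to 0.03) and Spearman's rho was 0.02. Among 1432 loci with at least 500 reads in every library r was 0.12 (0.03 to 0.21) and rho 0.17, and among 1797 loci with a mean of at least 500 reads r was 0.06 (-0.02 to 0.15) and rho 0.13. These are correlations across loci, which are not independent replicates. Of the loci, 7 were at least 2-fold higher with exudates at both times, where independent lists of these sizes would share 5.43, and 5 were lower at both, where 6.27 would be shared. A further 20 loci were higher at 24 h and lower at 48 h, against 7.77 for independent lists, and 7 were lower at 24 h and higher at 48 h, against 4.38. These expected numbers have no spread, and neighbouring loci had similar ratios, so no excess over them was tested. The effects of exudates differed between the times by at least 2-fold for 674 loci, of which 332 had the higher ratio at 48 h and 342 the lower. Total-read scaling turned this into 257 and 482, median-ratio factors into 384 and 299, and the deposited RPM values into 443 and 403, so the balance has no direction that holds under these scalings. V529_31610 had a log2 ratio of exudates to control of -2.97 at 24 h and of 0.76 at 48 h. V529_03850 went the other way, with log2 ratios of 1.43 at 24 h and -2.42 at 48 h. No test of these differences exists without replicate libraries.

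**Figure D2:**
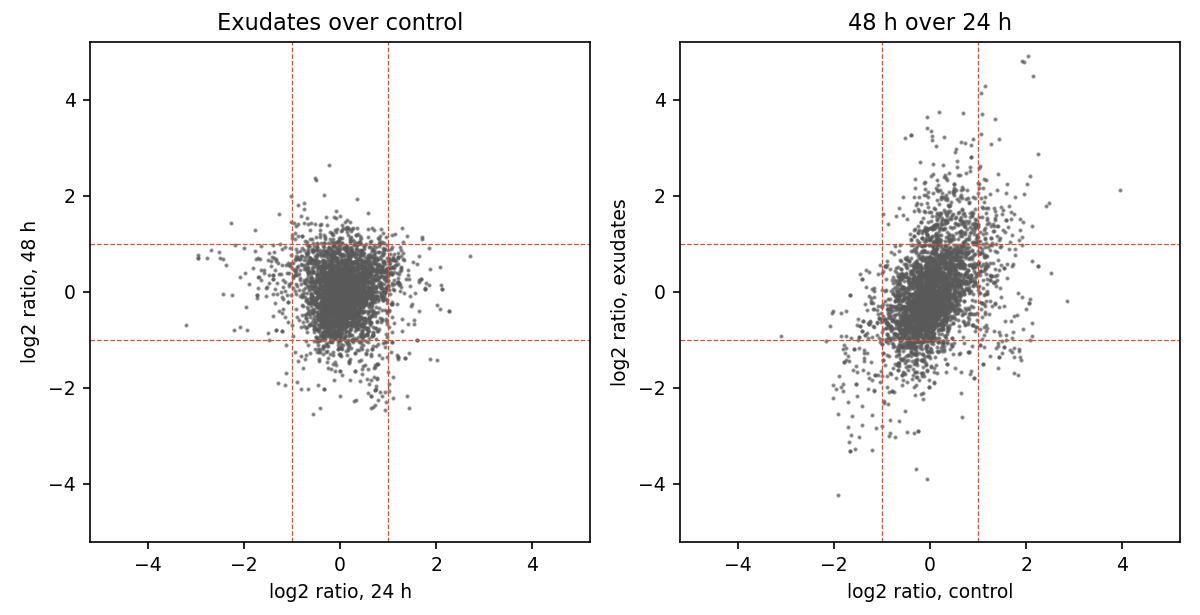
Each point is a locus. The left panel sets the log2 ratio of exudates over control at 48 h against that at 24 h, and the right panel the log2 ratio of 48 h over 24 h with exudates against that in control, with dashed lines at 2-fold. The left cloud has no slope (r = -0.04) and the right one rises (r = 0.45).

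Between 24 h and 48 h in water control, higher loci outnumbered lower ones. Of 3776 loci kept, 264 were at least 2-fold higher at 48 h and 136 at least 2-fold lower. With the deposited RPM values this turned to 212 higher and 345 lower, 231 of the lower loci in the second set. Runs numbered 8, against at most 1 in any of 1000 shuffled orders. The longest run, at positions 1559 to 1587, held 29 loci that were higher at 48 h by a median of 2.82-fold, between 2.08-fold and 4.22-fold. At these positions the median log2 ratio of exudates to control was 0.73 at 24 h and -1.79 at 48 h, and that of 48 h to 24 h with exudates was -0.90. The 3 runs of lower loci lay at positions 3378 to 3386 (median 3.01-fold), 3417 to 3430 (13 loci, median 3.13-fold) and 3476 to 3482 (median 3.55-fold). V529_33540 was 18.0-fold higher at 48 h (9.49 to 45.6), with 126 reads against 8. This ratio uses the same 48 h control library as its lower ratio with exudates at 48 h given above. V529_21410 had 45 reads at 48 h and 3 at 24 h, a ratio of 15.5 with an interval of 5.89 to 92.4. These ratios rest on few reads at 24 h. With a pseudocount of 5 reads the log2 ratio went from 4.17 to 3.53 for V529_33540 and from 3.96 to 2.78 for V529_21410. With the deposited RPM values, each raised by 1 before taking log2, it was 3.32 for V529_33540 and 3.34 for V529_21410. V529_03000, a coding region of 282 bp, had 53755 reads at 24 h and 5139 at 48 h, 8.54-fold lower (8.30 to 8.80). This locus and V529_33540 are in the second set, where the total used for the 24 h control is 55.3% of its reads. That lowers the ratios of 48 h to 24 h in control taken from the deposited RPM values. For V529_03000 the log2 ratio was then -3.91 in place of -3.10. V529_17970 was 4.46-fold lower (4.17 to 4.79).

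With exudates, the time difference covered more loci than without. Of 3792 loci kept, 467 were at least 2-fold higher at 48 h than at 24 h and 392 at least 2-fold lower, 22.7% of loci against 10.6% in control. The median log2 ratio of all loci was -0.12. With total reads only it was -0.24, and the counts became 398 higher and 506 lower. The deposited RPM values gave 384 and 515, and median-ratio factors 514 and 340. The interval excluded 1 for 857 of the 859 loci, again largely by that choice. Across loci, the log2 ratio had a Spearman's rho of -0.18 with coding length and of -0.19 with abundance. V529_26030 had 129 reads at 24 h and 4066 at 48 h, 29.9-fold higher (25.1 to 36.0). V529_26000 had 193 and 5666 reads, 27.8-fold higher (24.2 to 32.4). The rows between these tags, at ranks 3 and 4, were 27.4-fold and 22.5-fold higher. V529_32690 was 18.7-fold lower at 48 h (14.4 to 25.3), and V529_03850 was 15.0-fold lower (10.8 to 21.9). There were 20 runs with 143 loci, 10 in each direction, against at most 2 runs in any of 1000 shuffled orders. The longest held 25 loci at positions 127 to 151, lower at 48 h by a median of 2.54-fold, where the median log2 ratio of 48 h to 24 h in control was -0.46. A run of 5 loci at positions 3161 to 3166 was higher by a median of 10.3-fold, and had a median log2 ratio of exudates to control of -2.68 at 24 h and 0.76 at 48 h. The run at positions 3939 to 3946 was lower by a median of 7.14-fold and overlaps the run that was higher with exudates at 24 h. Both runs use the library with exudates at 24 h, so the overlap is no second observation.

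The time differences in the 2 media, which share no library either, went together. Pearson's r across 3749 loci was 0.45 (block bootstrap interval 0.38 to 0.52) and Spearman's rho 0.46. At 48 h, 94 loci were at least 2-fold higher in both media, where independent lists would share 30.5, and 65 were lower in both, where 13.8 would be shared. The runs at positions 3378 to 3386 and 3476 to 3482 were lower at 48 h in both media, by medians of 3.01-fold and 3.55-fold in control and 7.45-fold and 4.01-fold with exudates. A further 27 loci were higher over time in control and lower with exudates, against 26.4 for independent lists. No locus went the opposite way (0 loci, against 15.9). Here too the expected numbers have no spread and neighbouring loci had similar ratios, so no departure from them was tested.

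**Figure D3:**
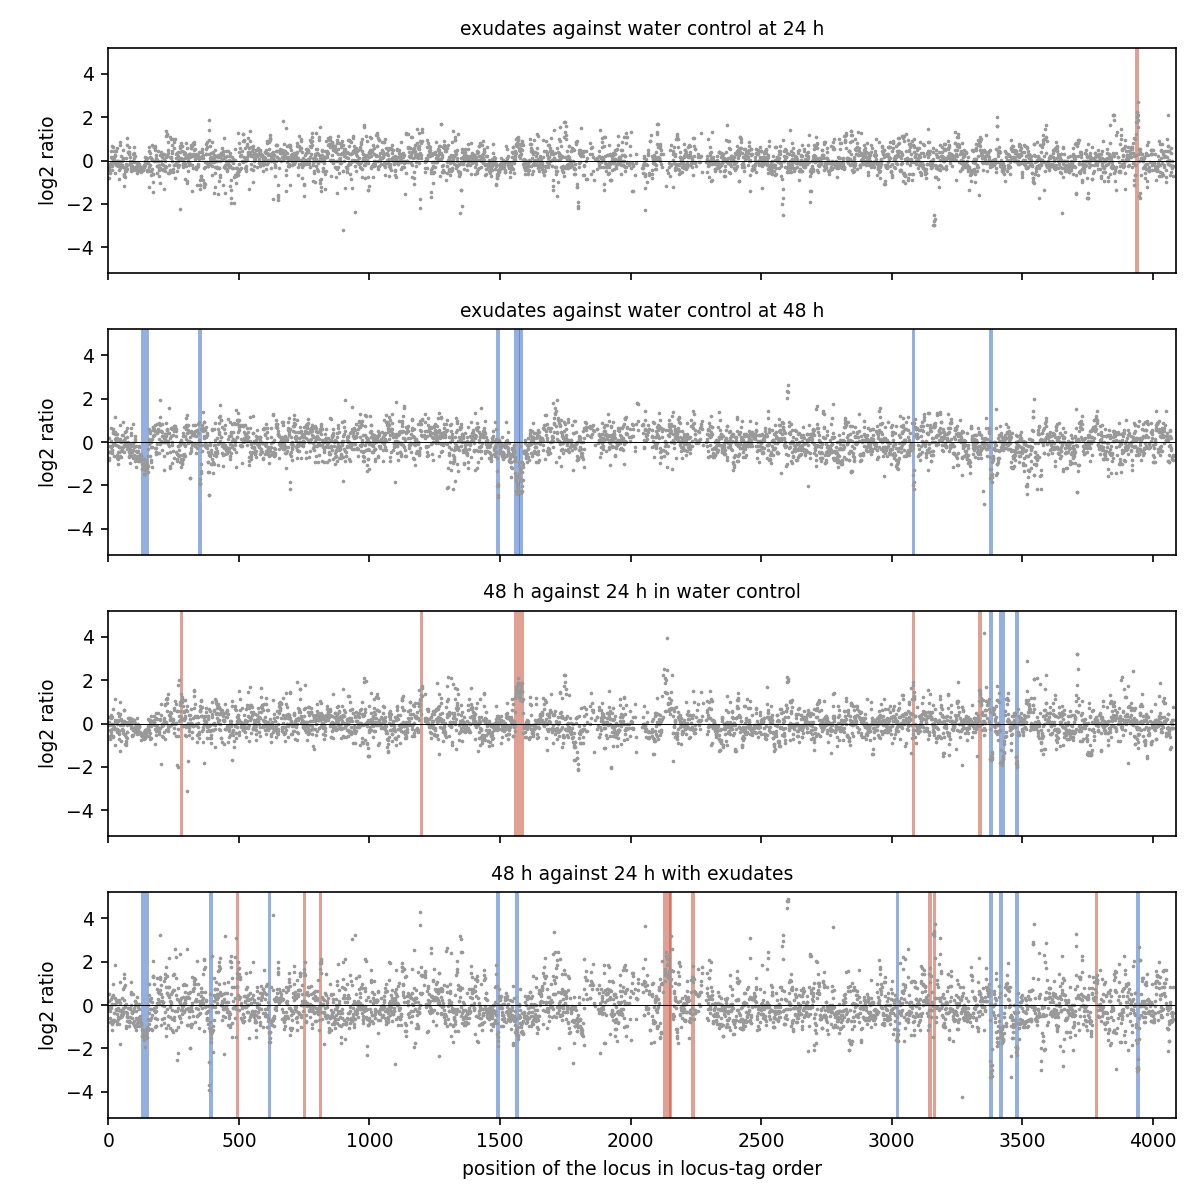
Log2 ratio of each locus (grey points) against its position in locus-tag order, 1 panel per comparison. Shaded bands, widened by 4 positions on each side, mark runs of at least 5 adjacent loci higher (red) or lower (blue) by at least 2-fold, such as the run at positions 1559 to 1587 in the control panel.

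In the additive fit over all 4 libraries, no locus passed an adjusted p of 0.05 for the average exudate effect over both times with edgeR's quasi-likelihood test. There were 0 calls among 3819 loci, the smallest adjusted p was 0.92, and 174 loci had an unadjusted p under 0.05. DESeq2 and limma also gave 0 calls, with 115 and 188 loci at an unadjusted p under 0.05. None of these counts exceeds the share of 0.05 of the loci that would pass without any effect. For the average time effect over both media, edgeR gave 0 calls, with a smallest adjusted p of 0.070 and 648 loci at an unadjusted p under 0.05, and limma gave 0 calls with 674. The counts of 648 and 674 exceed a share of 0.05 of the loci, but loci are not independent, so this is no test. DESeq2 called 147 loci at an adjusted p under 0.05, 75 higher and 72 lower at 48 h. It gave no adjusted p for 963 of the 3819 loci. The spread in this fit is the departure from additivity and rests on 1 residual degree of freedom. Fits that left out 1 library, with the medium dropped from the model, leave 1 library at 1 of the times. Its spread is assumed to be that of the others, and the other time holds both media. Time is then mixed with medium, so calls from these fits are not counted as an average time effect.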

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

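The tests on the deposited columns, the covariance, the mean of at least 500 reads, the share of counting variance and the count of loci that differ between the times were chosen after the results had been seen, as were the run rule and the choice of rows to leave out. The tests at 500 reads in every library, without the doubtful rows, at a distance of 3 rows and after subtracting a running median were added after other results had been seen, with their outcomes set out before they were run.

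A first result comes from columns that the comparisons above do not use. In 803 loci the deposited fold change is another ratio than in the larger set of 3238 loci. In the control table it is 24 h over 48 h in place of 48 h over 24 h. In the exudate table it is exudates at 24 h over 48 h in place of exudates over control at 48 h. If the read columns themselves were swapped in these loci, their ratios of 48 h over 24 h reported here would be reversed. The fall of the denominators of the deposited RPM values across a skipped row gives an estimate of the reads of that row. Listed and recovered reads were at least 20 throughout for 255 of the loci. Listed and recovered log2 ratios of 48 h over 24 h in control had r = 0.80 across loci, and 0.84 with exudates. A swap would give a negative r, so this argues against a swap. The recovered reads are not the same as the listed ones, and why they differ was not tested. In all 803 loci the RPM value follows from 1 fixed total per library and the coding length, consistent with a separate normalization run for these loci. That total is 55.3% of the reads in the 24 h control and 100% in the other libraries, so the second-set RPM values of the 24 h control are too high against the rest.

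In 227 pairs of rows the counts are identical in all 4 libraries. No explanation was tested. With these pairs left out of the comparisons, the loci at least 2-fold apart at 24 h numbered 125 higher and 108 lower with exudates.

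The exudate effects went in opposite directions at the 2 times for 27 loci, each at least 2-fold. The difference was not tested, since each time has 1 library per medium. More widely, the effects at 24 h and 48 h were close to unrelated over all loci. Counting error made up at most 8.74% of the variance of the log2 ratios, and leaving out the second set and the identical pairs gave r = -0.025 over 2565 loci, which argues against both as the cause. Independent variation of single libraries would lower r but leave the covariance, whose interval ended at 0.00924 over all loci, but ran from 0.011 to 0.059 among 1432 loci with at least 500 reads in every library and from -0.0078 to 0.049 among 1797 with that mean, so a weak shared effect stays open. In the first of these sets r was 0.12, between the outcomes set out for counting noise at few reads, and a minimum in every library drops loci low in 1 of them, so that test did not decide either. A response to exudates that changes with time (674 loci differ by at least 2-fold) and culture differences that move many loci at once cannot be told apart with 1 library per group.

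Over time, 27 loci were at least 2-fold higher at 48 h in control and at least 2-fold lower with exudates, and 13 of them lie at positions 1559 to 1587. This difference was not tested.

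Neighbouring loci had similar ratios of exudates to control at 48 h, with r = 0.50 between adjacent rows. Reads shared between adjacent rows would not reach 3 rows away, where r was 0.28 (identical pairs left out). The highest r of 1000 shuffled orders was 0.061, computed between adjacent rows only. Adjacent rows had r from 0.40 to 0.49 in the other 3 comparisons. A running median was also subtracted, with a window far longer than 20 rows, after which r between adjacent rows was 0.45. This removes only a smooth trend along the chromosome that is wider than the window, and a narrower trend would remain. The r at 3 rows argues against shared reads as the whole cause, and the r after subtraction against such a wide trend. The r was still 0.14 at 10 rows and 0.15 at 20 rows. The source of this wider similarity, a narrower trend included, was not tested, nor was any biological explanation.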

How the results depend on the processing

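No paired analysis was possible because each group holds 1 library with the same replicate number; the additive fit compares the media within each time instead. Gene list alternatives were not run, since no list symbol occurs in the tables. The identical-pair and second-set alternatives were chosen after seeing the data. Thresholds moved every count of loci by size: at 4-fold, exudates against control gave 10 higher and 18 lower at 24 h and 5 and 32 at 48 h, 48 h against 24 h gave 27 and 7 in control and 105 and 49 with exudates, and the difference of exudate effects gave 62 and 76. At 1.5-fold, the same counts were 537 and 318, 595 and 619, 599 and 427, 807 and 954, and 653 and 848. Scaling by total reads gave 83 higher and 325 lower with exudates at 48 h. The deposited RPM values gave 345 lower at 24 h with exudates, 80 higher and 320 lower at 48 h, and 345 lower over time in control. In the 2 comparisons with the 24 h control, 248 and 231 of these 345 were second-set loci, whose log2 ratios shifted by a median of -0.86 and -0.81 with the smaller total used there, against -0.05 and 0.00 in the other loci. Median-ratio factors, both pseudocounts, both count filters, the most abundant 1% left out of scaling, and the identical pairs or the second set left out kept all counts of loci by size within 1.5 times. Runs numbered 0, 1, 0 and 3 at 4-fold and 16, 25, 19 and 44 at 1.5-fold in the 4 comparisons, and 3 at 24 h with the deposited RPM values. The correlation of exudate effects ran from -0.040 to 0.003 under 6 alternatives, within its bootstrap interval. Of these, total-read and median-ratio scaling shift all ratios of a comparison by nearly the same amount, so they could hardly change r. The correlation left the interval at 0.12 with at least 500 reads in every library and at 0.060 with that mean. Both were added after seeing the data, the first with its outcomes set out before it was run. For the average exudate effect, leaving out each library, with time dropped from the model as well, gave 0 to 1 calls, and the 1 call came without the 24 h control. For the average time effect, with the medium dropped, it gave 0 to 269 calls (77 without the 24 h control, 269 without the 48 h control, 9 without exudates at 48 h), with the lone library of a group assumed to vary like the others, and DESeq2 gave 147. No other setting of either fit gave a call, and the cause of these differences was not tested. Of 154 alternative values of the 16 named ratios 149 stayed within the counting interval, but these ratios were picked as the largest, so their direction under the alternatives shows no stability. Depth limits loci under about 20 reads, whose intervals span several fold.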

Other observations

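The 41 loci most abundant with exudates at 48 h held 31.3% of the reads there, 19.5% in the 48 h control, 14.6% in the 24 h control and 14.2% with exudates at 24 h. Of these 41, 27 were at least 2-fold higher and 1 lower at 48 h than at 24 h with exudates, and 7 were higher over time in control. They were picked for their level in that library, so their direction against it is not independent of the choice.

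Short loci stood higher than long ones at 48 h with exudates. The median log2 ratio to the 48 h control was 0.21 for the shortest loci (coding length up to 363 bp) and -0.11 for the longest (from 1263 bp), with a Spearman's rho of -0.16 with coding length across loci. At 24 h the medians were 0.04 and 0.05, with a rho of 0.03. Between 24 h and 48 h with exudates the medians were 0.20 for the shortest and -0.28 for the longest loci, with a rho of -0.18, and 0.29 for the least and -0.32 for the most abundant loci, with a rho of -0.19. In control the rho was -0.08 with length and -0.19 with abundance.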
